A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

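Total RNA of 6 samples from log-phase culture, 3 of the mutant BH13 and 3 of the reference strain (REF), was labelled with Cy3 and hybridised to Agilent one-colour yeast expression arrays, per the labels' protocols. Group and replicate number were taken from the sample labels. The labels speak of 3 replicates of each culture and do not say whether these were started separately, so p-values measure the spread between these samples, which may be partly technical. The deposited scanner files hold spot intensity on a linear scale, background-subtracted by Agilent Feature Extraction 10.7.3.1 per the file headers, while the submitters' processing notes name Agilent Feature Extraction 9.1. The deposited table of the authors' processed values holds log2 values for 1325 probes, and its filter and normalization are not given in the sources used here.

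Each array had 12512 gene spots for 6256 probes, 2 spots per probe and 1 probe per gene, so no gene had probes that could disagree. Control spots and feature outliers were left out, spots of a probe were averaged as log2 processed signal, and each array's 75th percentile over gene spots was subtracted. That percentile was between 2301 and 4905 intensity units. Probes well above background on at least 3 of the 6 arrays were kept, which gave 5890 genes and left out 366. Systematic names were matched to the RefSeq gene table of assembly R64, used for names, chromosomes and gene lengths, and 5756 of 6256 matched. The other 500 keep the array's own name. Where a probe was not well above background on any array of a strain, the fold is a bound. It sets the bright strain's mean against the mean, over the dim strain's arrays, of the higher of the probe's own value and the lowest value among probes well above background. Such a bound applies to the processed signal, and background corrections that add an offset give smaller differences for dim probes.

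Strains were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Permutation of 3 arrays against 3 cannot give a p below 0.1, so no such test was made for single genes. The 37 gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Gene lists, the gene and list tests, all alternatives but one and the rule for the genes named were fixed before the data were examined. The rule takes the 12 largest increases and 12 largest decreases among called genes whose 3 values per strain do not overlap, that have a standard symbol and are well above background on all arrays of the brighter strain. It adds up to 4 called members with the largest differences from each list, the 2 largest in each cell type or growth check list, and YAP1, PDR1, MSN2 and MSN4. The rule named 152 genes, of which the text gives a part. FUS1, RIM15 and AAD4 were named after their values were seen.

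Data were simulated for this comparison with 5890 genes, the REF means for both strains and each gene's average variance within strains. The gene test recovered 22% of 50 genes changed 1.25-fold, 66% at 1.5-fold, 92% at 2-fold and 100% at 4-fold. It called 7 of 5690 unchanged genes. Most simulated genes were thus unchanged, whereas 81.3% of genes were called in the real data. The Benjamini-Hochberg cutoff was therefore stricter in the simulation, and these shares do not describe the real test. The list test called the 1 list that was shifted 2-fold and none of the other 36. Genes were simulated independently, and the other lists were left unchanged. The simulation therefore cannot show how the list test behaves when members are correlated, and the general stress list had an estimated correlation of 0.50.

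Agilent's spike-in transcripts were not used for scaling, because the mean of the 7 detected ones ranged from 0.06 to 1.09 between REF arrays after scaling. The alternatives were normexp background correction with an offset of 50, median centring, quantile and cyclic loess normalization, no filter on dim probes, a filter on all 6 arrays, outlier spots kept, an intensity trend with robust variance, the authors' table, the replicate number as a block, the slide as a random block, and each array left out. Normexp used median signals, because mean signals are not among the columns used here. Leaving out spots with an uneven background was added after the data were seen. The brightest-probe alternative was not run, since each gene had 1 probe.

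The authors' table was set against the scanner values. Each of its rows has a median of 0 over the 6 arrays to within rounding, and its column medians were -0.58, -0.53 and -0.55 for BH13 and 0.56, 0.60 and 0.52 for REF. Its strain differences had a slope of 1.00 and a Pearson r of 0.999 across probes against those from the scanner values. The sign was the same for all 1325 probes, so scale, centring and direction could be told. Every probe in it was called, and the smallest difference was 0.92 in size, so it held probes that differed between strains. Agreement in sign thus says nothing about probes with small differences. The exact rule that chose its probes could not be told, since 788 probes at least 2-fold apart on the scanner values were not in it.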

Results

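The series compared RNA from BH13, a mutant of the budding yeast Saccharomyces cerevisiae selected for better resistance to coniferyl aldehyde, with RNA from its reference strain, called REF here. Coniferyl aldehyde is a phenolic aldehyde released from lignin that inhibits yeast growth. The comparison asks how the transcriptome of the mutant differs from that of the reference strain in untreated log-phase cultures in minimal medium. Each strain had 3 samples, each on its own one-colour array, and the labels call them replicates of the culture. Of 12512 gene spots per array, 91.4% to 93.8% were well above background, and none was saturated. Negative control spots had a mean net signal of 58.2 to 63.5 on the BH13 arrays and 27.4 to 31.9 on the REF arrays. Correlations of log2 signal across the 5890 genes tested were 0.994 to 0.998 between arrays of one strain and 0.854 to 0.877 between strains, with genes not being independent replicates. Differences below are log2 values, BH13 minus REF, ± the standard error from limma, with n = 3 arrays per strain. The number of arrays limits their precision.

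BH13 and REF differed across most of the genome. The largest increases in BH13 included CYC7, the hypoxic isoform of cytochrome c, by 7.98 ± 0.17, and HSP12, a small membrane-protecting stress protein, by 6.64 ± 0.18. The largest decreases included STE2, the receptor for alpha-factor, which fell by 7.59 ± 0.11, and MFA1, a gene for the a-factor pheromone, which fell by 7.72 ± 0.22. With normexp background correction these shrank to 6.90 for CYC7, -6.11 for STE2 and -5.00 for MFA1. By limma with Benjamini-Hochberg adjustment, 2240 genes were higher and 2549 lower in BH13, which together is 81.3% of the genes tested. At least 2-fold differences were found for 1056 genes that rose and 1033 that fell. The 3 BH13 values lay wholly above or below the 3 REF values for 83.7% of genes, where chance gives 10%. The BH13 arrays shared 1 slide and 1 day of scanning, and the REF arrays lay on 2 other slides scanned on another day. Strain and day of scanning therefore cannot be told apart. With the slide as a random block 2199 genes were higher and 2511 lower. Slides differ within a strain only among the REF arrays, so these counts do not test a slide or day effect.

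The genes of the a mating type and of haploid cells fell together in BH13. All 7 measured a-cell markers were lower, with a median difference of -4.19, and 9 of 10 haploid-specific genes were lower, with a median of -2.92. Both counts were the same adjusted over the list alone. HO, the mating-type switching endonuclease, was not well above background on any BH13 array and was at least 297-fold lower than in REF (limma adjusted p = 1.43e-08). MFA2, the second a-factor gene, was at least 182-fold lower and AGA2, an a-agglutinin subunit, at least 12.7-fold lower on the same basis. MFA1 was well above background on 1 of the 3 BH13 arrays, and FAR1, which arrests the cell cycle in response to pheromone, on 2. FUS3, the mating MAP kinase, fell by 6.01 ± 0.12, FAR1 by 5.32 ± 0.15, and STE4, the G protein beta subunit of the mating pathway, by 3.25 ± 0.10. FUS1, a cell fusion gene, was the exception in the haploid list and was higher by 0.40 ± 0.08. These bounds and sizes hold for the processed signal, and with normexp background correction the log2 differences were -5.56 for HO, -4.86 for MFA2, -1.55 for AGA2, -4.93 for FUS3 and -3.43 for FAR1. By camera in limma, adjusted p was 0.000583 for the a-cell list and 0.000692 for the haploid list, and with an estimated correlation adjusted p = 0.324 for both.

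**Figure D1:**
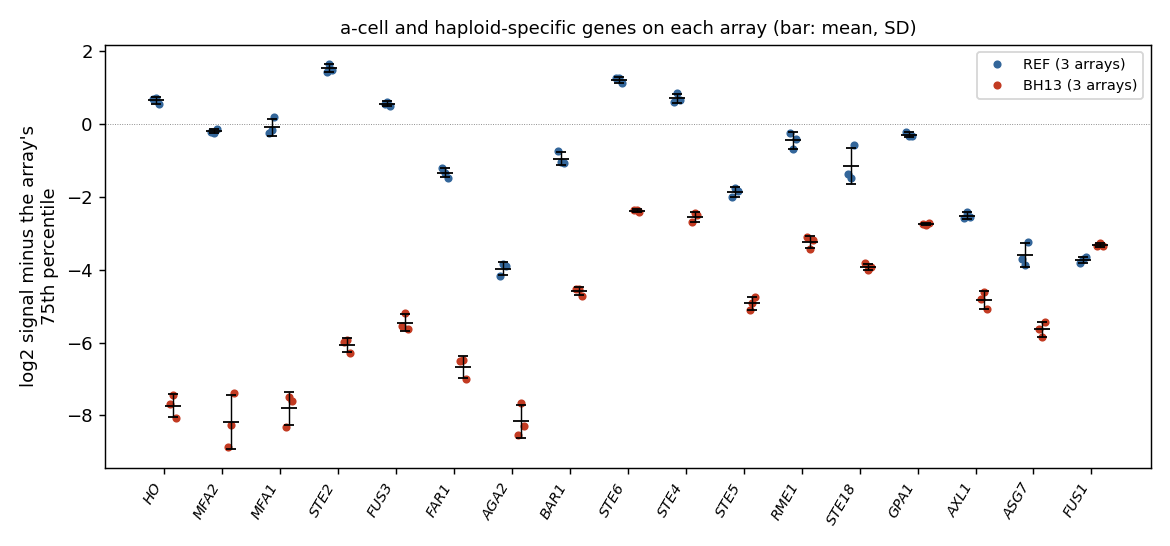
Log2 signal relative to each array's 75th percentile (vertical axis) for the measured a-cell and haploid-specific genes (horizontal axis). Each point is an array, blue for the 3 REF arrays and red for the 3 BH13 arrays, with bars for the mean and SD. The BH13 points lie below the REF points for every gene shown except FUS1, which was higher by 0.40.

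Lists of alpha-cell, meiotic and S-phase genes were not called. Of 4 alpha-cell markers, MF(ALPHA)1, an alpha-factor gene, rose by 1.07 ± 0.17 and STE3, the a-factor receptor, by 0.44 ± 0.08, while AFB1 fell by 1.45 ± 0.19 with camera adjusted p = 0.679 for the list. Of 15 meiosis and sporulation genes, 8 were higher and 6 lower (camera adjusted p = 0.394). SPO20 rose by 2.82 ± 0.14, DIT1 by 2.36 ± 0.11 and SPO13 by 1.59 ± 0.20, and SPS4 fell by 1.43 ± 0.13. IME4, an mRNA methyltransferase needed for entry into meiosis, was not well above background on any REF array and was at least 135-fold higher in BH13. With normexp background correction the differences were 3.68 for IME4, 2.17 for SPO20, 0.86 for SPO13, -0.75 for SPS4 and -0.68 for AFB1. In the list of histone and S-phase genes, 5 of 20 were higher and 10 lower (camera adjusted p = 0.443). Its members with the largest changes were the G1 cyclin genes CLN2, which fell by 2.74 ± 0.08, CLN1, which fell by 1.57 ± 0.08, and PCL1, which fell by 1.51 ± 0.08.

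Genes of the general stress response rose in BH13. The list of 28 measured genes holds targets of the transcription factors Msn2 and Msn4 and 3 regulators, MSN2, MSN4 and the kinase gene RIM15. Of these genes 27 were higher and none was lower, over all genes and adjusted over the list alone, with a median difference of 2.90. TMA10 rose by 6.88 ± 0.23, HXK1, a hexokinase isoenzyme, by 6.67 ± 0.15, and ALD3, an aldehyde dehydrogenase, by 4.61 ± 0.17. MSN2, with a difference of 0.16 ± 0.10, was the member that did not pass (limma adjusted p = 0.167), although it was called higher, at 0.23, with normexp background correction (limma adjusted p = 0.0398). MSN4, counted among the 27, differed by 0.20 ± 0.07, and its call was lost under 6 alternatives, where limma adjusted p was at most 0.117. Among trehalose and glycogen genes, 15 of 18 were higher and 1 lower, led by glycogen phosphorylase GPH1 at 6.40 ± 0.17, phosphoglucomutase PGM2 at 4.52 ± 0.14 and the trehalose synthase subunit TSL1 at 4.42 ± 0.18. Of 25 heat shock proteins and chaperones, 20 were higher and 3 lower, with HSP26 at 5.61 ± 0.13, SSA4 at 3.97 ± 0.23 and HSP82 at 3.34 ± 0.11. Of 18 genes of cells leaving log phase, 14 were higher and 1 lower, among them SPG4 at 3.95 ± 0.25 and FMP16 at 3.90 ± 0.18, and SPG4 shrank to 2.23 with normexp background correction. By camera, adjusted p was 3.16e-09 for general stress, 2.19e-05 for trehalose and glycogen, and 0.000425 for both heat shock and post-diauxic genes. With an estimated correlation, adjusted p was 0.547 for the first 3 lists and 0.598 for the post-diauxic list.

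**Figure D2:**
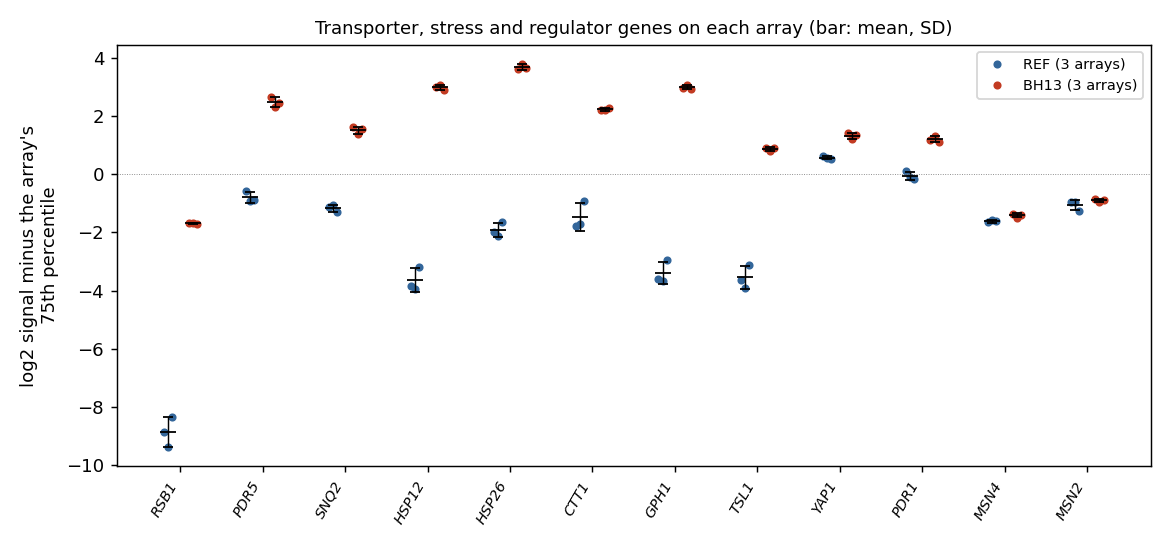
Log2 signal relative to each array's 75th percentile (vertical axis) for transporter, stress and regulator genes (horizontal axis). Points are arrays, blue for REF and red for BH13, and bars give the mean and SD of 3 arrays. HSP12 lies 6.64 higher in BH13, whereas MSN2 differs by 0.16.

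Among genes that act on aldehydes and oxidants, most called members were higher. Of 28 genes for aldehyde reduction and oxidation, 21 were higher and 4 lower (camera adjusted p = 0.000479, and adjusted p = 0.598 with an estimated correlation). BDH2 rose by 4.81 ± 0.12 and the mitochondrial aldehyde dehydrogenase gene ALD4 by 4.51 ± 0.12, while the alcohol dehydrogenase gene ADH4 fell by 4.44 ± 0.16. ADH4 was well above background on 2 of the 3 BH13 arrays, and its difference was -2.56 with normexp background correction. Of 26 genes of oxidative stress and thiol redox, 19 were higher and 1 lower (camera adjusted p = 0.000315, and adjusted p = 0.471 with an estimated correlation). Thioredoxin TRX2 rose by 3.89 ± 0.11, cytosolic catalase CTT1 by 3.71 ± 0.21, sulfiredoxin SRX1 by 2.70 ± 0.18 and peroxiredoxin TSA2 by 2.70 ± 0.11, with SRX1 at 1.78 after normexp background correction. YAP1, which encodes the main transcription factor of the oxidative stress response, rose by 0.76 ± 0.08. All of these counts were the same adjusted over the list alone.

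The putative aryl-alcohol dehydrogenases were split, with AAD15 higher by 2.29 ± 0.10, AAD14 higher by 0.93 ± 0.08, AAD4 higher by 0.36, AAD6 lower with a difference of -0.79 ± 0.17 and AAD10 lower with a difference of -0.38 ± 0.08. AAD15 was well above background on 2 of the 3 REF arrays. With normexp background correction AAD15 was at 0.86, and AAD6 at -0.35 was no longer called (limma adjusted p = 0.0642). That list of 5 genes was not called (camera adjusted p = 0.489). The family members resemble one another, so a probe of one may also read another. In the list for aromatic amino acid catabolism and phenylacrylic acid decarboxylation, 6 of 13 genes were higher and 4 lower (camera adjusted p = 0.421). The decarboxylase gene ARO10 rose by 3.17 ± 0.15 and the pyruvate decarboxylase gene PDC6 by 2.65 ± 0.12, and PDC5, another pyruvate decarboxylase gene, fell by 3.43 ± 0.24. ARO10 was well above background on 2 of the 3 REF arrays, and its difference was 1.35 with normexp background correction.

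The multidrug list held RSB1, among the 12 largest increases on the processed signal, and members that fell. RSB1, which encodes a membrane protein that exports sphingoid bases, was not well above background on any REF array and was at least 140.1-fold higher in BH13 (limma adjusted p = 6.21e-08). The ABC transporter genes PDR5 and SNQ2 rose by 3.26 ± 0.12 and 2.69 ± 0.10, and PDR1, which encodes their main activator, rose by 1.27 ± 0.10. AQR1, which exports amino acids and weak acids, fell by 3.29 ± 0.10. With normexp background correction the differences were 3.84 for RSB1 and -2.65 for AQR1. Of the 31 genes in the multidrug list, 16 were higher and 14 lower, and the list as a whole was not called (camera adjusted p = 0.490).

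Lists of respiratory, gluconeogenic and glycolytic genes were called higher in BH13. Of 35 nuclear genes of the respiratory chain and ATP synthase, 25 were higher and 7 lower (camera adjusted p = 0.000579, and adjusted p = 0.547 with an estimated correlation). COX7 rose by 4.07 ± 0.13, COX5B, the hypoxic isoform of a cytochrome oxidase subunit, by 3.88 ± 0.14, and QCR9 by 3.16 ± 0.15. Of 16 genes of gluconeogenesis and the glyoxylate cycle, 12 were higher and 1 lower (camera adjusted p = 0.00396, and adjusted p = 0.598 with an estimated correlation), with SFC1 at 2.82 ± 0.29, CIT3 at 2.56 ± 0.14 and PCK1 at 1.99 ± 0.24, and SFC1 was at 1.76 with normexp background correction. Of 19 glycolytic genes, 9 were higher, 1 lower and 9 not called (camera adjusted p = 0.0166, and adjusted p = 0.652 with an estimated correlation). The median of that list was only 0.26, and PGI1 at 0.05, CDC19 at 0.18 and PGK1 at 0.20 were among the members not called. The call for glycolytic genes ended with quantile normalization (adjusted p = 0.189). The largest differences in the glycolytic list were those of HXK1, given above, GPM2 at 4.48 ± 0.12 and the glucokinase gene GLK1 at 2.67 ± 0.16. HXK1 and GLK1 are also in the general stress list.

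Other carbon lists had large single changes without a list call. The transporter genes HXT7 and HXT6 were higher by 5.10 ± 0.12 and 4.95 ± 0.13, but these genes are nearly identical and their probes may not separate them. Of 16 hexose transport genes, 10 were higher and 4 lower (camera adjusted p = 0.108), and the list was called higher with no filter on dim probes (adjusted p = 0.0370, and adjusted p = 0.565 with an estimated correlation). In the pentose phosphate list, 9 of 14 genes were higher and 4 lower (camera adjusted p = 0.141), led by NQM1 at 4.86 ± 0.11 and SOL4 at 4.21 ± 0.16. Of 19 genes of the tricarboxylic acid cycle, 11 were higher and 5 lower (camera adjusted p = 0.162), with CIT1 at 1.71 ± 0.10 and IDH2 at 1.49 ± 0.08. Of 21 genes of peroxisomal fatty acid oxidation, 9 were higher and 7 lower (camera adjusted p = 0.380), with CRC1 at 2.98 ± 0.15, or 2.10 with normexp background correction.

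Genes for making ribosomes fell in BH13. All 39 measured ribosome biogenesis factors were lower, 38 of them at least 2-fold, with a median difference of -1.81 (camera adjusted p = 6.05e-11, and adjusted p = 0.471 with an estimated correlation). The RNA helicase gene DBP2 fell by 4.34 ± 0.09, the helicase gene DBP9 fell by 2.90 ± 0.08 and the pseudouridine synthase gene CBF5 fell by 2.76 ± 0.07. The 137 cytosolic ribosomal protein genes had a median of -0.37, with 37 higher and 79 lower, and the list was not called (camera adjusted p = 0.0769). It was called lower under 4 alternatives, at adjusted p = 0.0197 with quantile normalization, where adjusted p = 0.523 with an estimated correlation. RPL21A fell by 2.23 ± 0.10 and RPS10B rose by 1.72 ± 0.08, and many ribosomal protein genes have a close duplicate that the same probe may read. Mitochondrial ribosomal protein genes went both ways, with 21 of 56 higher and 26 lower (camera adjusted p = 0.840). Of 33 proteasome genes, 20 were higher and 5 lower, with a median of 0.33 (camera adjusted p = 0.0119, and adjusted p = 0.471 with an estimated correlation), and PRE2 rose by 1.57 ± 0.08.

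**Figure D3:**
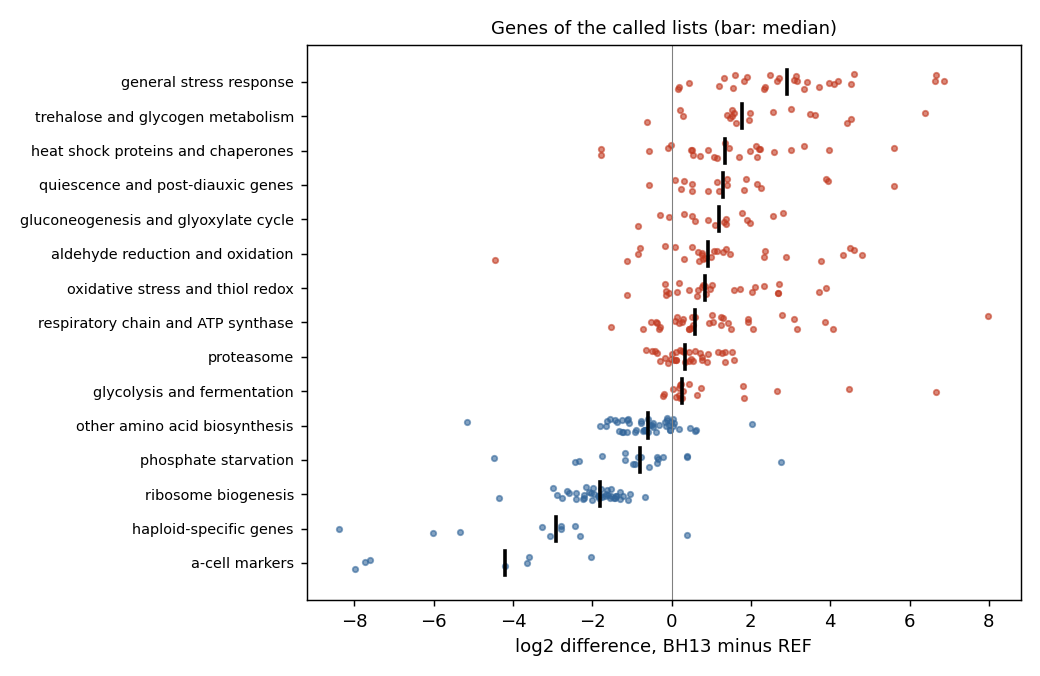
Log2 difference, BH13 minus REF (horizontal axis), of the genes in each of the 15 lists called by camera (vertical axis). Points are genes, red where the list's median is above 0 and blue where it is below, and black bars are medians. The general stress list has a median of 2.90 and the ribosome biogenesis list a median of -1.81.

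Genes of amino acid synthesis and phosphate supply were mostly lower. In the list of other amino acid biosynthesis, which holds GCN4 and synthesis genes for lysine, leucine, histidine and others, 31 of 47 were lower and 4 higher (camera adjusted p = 0.00121, and adjusted p = 0.547 with an estimated correlation). GCN4, an activator of amino acid synthesis genes, fell by 1.81 ± 0.08 and ILV5 by 1.65 ± 0.09, and GDH3 rose by 2.03 ± 0.08. ARO3, which catalyses the first step of aromatic amino acid synthesis, was not well above background on any BH13 array and was at least 17.7-fold lower, with a log2 difference of -1.90 after normexp background correction. Of 18 phosphate starvation genes, 14 were lower and 3 higher, and 15 were lower adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.471 with an estimated correlation). The phosphate transporter gene PHO84 fell by 4.48 ± 0.11 and the regulator gene PHO4 by 2.32 ± 0.09, and PHM8 rose by 2.77 ± 0.16. PHO84 was at -3.64 with normexp background correction.

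Nutrient lists that were not called still held large changes. Of 27 nitrogen catabolite repressed genes, 9 were higher and 15 lower (camera adjusted p = 0.443), with the amino acid permease gene DIP5 higher by 3.31 ± 0.12 and the ammonium permease gene MEP2 lower, at -3.19 ± 0.10. DIP5 was at 1.37 with normexp background correction. Of 13 arginine and ornithine genes, 4 were higher and 8 lower (camera adjusted p = 0.679), and arginase CAR1 rose by 3.22 ± 0.12. That list's median was -0.25 and its mean 0.03. Of 25 sulfate and methionine genes, 6 were higher and 12 lower (camera adjusted p = 0.279), and the sulfate permease gene SUL1 fell by 2.43 ± 0.09. SAM3, an S-adenosylmethionine permease gene outside that list, fell by 5.15 ± 0.09, or by 4.46 with normexp background correction. Of 24 iron uptake genes, 6 were higher and 16 lower (camera adjusted p = 0.108), with FTR1 at -2.58 ± 0.09 and FET3 at -2.28 ± 0.13.

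Of 17 zinc and copper genes, 4 were higher and 11 lower (camera adjusted p = 0.108), and the list was called lower when spots with an uneven background were left out (adjusted p = 0.0436, and adjusted p = 0.528 with an estimated correlation). The zinc transporter gene ZRT1 fell by 4.18 ± 0.15, while the copper metallothionein genes CUP1-1 and CUP1-2, which are copies of each other and cannot be separated by probe, were higher by 4.22 ± 0.16 and 4.09 ± 0.16. In the thiamine and pyridoxine list, 9 of 22 genes were higher and 10 lower (camera adjusted p = 0.796), and its median of 0.02 and mean of -0.03 differed in sign.

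Of 25 ergosterol genes, 6 were higher and 16 lower (camera adjusted p = 0.0973). ERG20, which encodes farnesyl pyrophosphate synthetase, fell by 5.68 ± 0.09 and ERG3 by 1.55 ± 0.08, and ERG28 rose by 1.58 ± 0.09. Of 32 cell wall genes, 11 were higher and 18 lower (camera adjusted p = 0.490), with the wall mannoprotein genes CWP1 higher by 3.69 ± 0.12 and TIR2 lower, at -3.74 ± 0.11. Of 24 seripauperin genes, a family of near-identical copies, 8 were higher and 5 lower (camera adjusted p = 0.513). In the list of heme, iron-sulfur and hypoxic genes, 9 of 19 were higher and 7 lower (camera adjusted p = 0.421), with HAP4, an activator of respiratory genes, higher by 1.43 ± 0.08 and HEM12 lower, at -2.57 ± 0.12.

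Of the other genes with the largest changes, EGO4 rose by 7.25 ± 0.29, CIS1 by 6.15 ± 0.23, RGI1 by 5.55 ± 0.23 and SDH6 by 5.16 ± 0.16. CIS1 was well above background on 2 of the 3 REF arrays. PCS60, a peroxisomal protein gene, was not well above background on any BH13 array and was at least 25.6-fold lower. With normexp background correction the log2 differences were 3.71 for CIS1 and -2.28 for PCS60.

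Camera called 15 of the 37 lists, 10 higher and 5 lower. No list was called with an estimated correlation, where 3 lists had an unadjusted p under 0.05. The loss of calls cannot be put down to correlation between members alone. It also held for the a-cell and haploid lists, whose estimated correlations were -0.073 and -0.0074. With an estimated correlation camera uses the 4 residual degrees of freedom. Fry in limma, run beside camera, asks whether members differ at all. Its unadjusted fry p was 7.2e-08 for the a-cell list and 4.79e-07 for the S-phase list, which camera did not call. Adjusted over the list alone, the counts of members were the same except in 4 lists. These were phosphate starvation with 15 lower, glycolysis with 0 lower, seripauperins with 7 higher and mitochondrial ribosomal proteins with 27 lower.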

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

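Leaving out spots with an uneven background was chosen after the data were seen. Over the 17 alternatives run on the scanner values, 4551 to 4980 genes were called, and the counts of genes higher and lower, and of those at least 2-fold apart, stayed within 1.5 times the reported ones. The authors' table, with 1325 probes, gave 581 genes higher, 744 lower and 574 at least 2-fold higher, fewer because fewer probes were in it. Every probe in it was called, and the smallest difference was 0.92 in size, so named genes in it could hardly lose a call. Normexp background correction gave 864 genes at least 2-fold higher and 821 lower, and reversed the sign of 12 genes called at least 2-fold apart. It made the fold over 1.5 times smaller for 39 of the 152 genes under the naming rule and larger by as much for 0. Dim probes such as those of IME4 and ARO3 were among the 39. This alternative changed the background method, added an offset of 50 and used median signals, so the change cannot be put down to 1 of these. With each array left out in turn, 2135 to 2254 genes were higher, 2407 to 2515 lower, 1030 to 1088 at least 2-fold higher, 1022 to 1044 at least 2-fold lower, and 15 to 16 lists were called. With the replicate block, 2269 genes were higher and 2576 lower and 15 lists were called. Whether the numbers pair the samples could not be told. Same-numbered arrays had correlations of deviations of 0.13, 0.24 and 0.0027. Those of replicates 1 and 2 were the highest for their arrays. BH13 replicate 3 correlated best with REF replicate 1, at 0.076, and REF replicate 3 with BH13 replicate 1, at 0.091. Of 152 genes under the naming rule, 149 stayed on their side of the threshold under each alternative that measured them, and the exceptions were AAD6 and MSN4, which lost a call, and MSN2, which gained one with normexp. Of the 15 called lists, 14 passed under all 16 alternatives run for lists, and the glycolytic list was lost with quantile normalization. The ribosomal protein list passed under 4, at adjusted p = 0.0197 at the lowest and 0.142 at the highest over all. The hexose transport list passed with no filter on dim probes (adjusted p = 0.0370, at most 0.219 over its alternatives) and the zinc and copper list without spots of uneven background (adjusted p = 0.0436, at most 0.264). With an estimated correlation, no list was called under any alternative run for lists. List tests were not run on the authors' table, which holds selected genes, or with the slide as a random block. Low signal limits 70 called genes that were not well above background on any BH13 array and 16 on any REF array.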

Other observations

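The tests for the slide, for glucose and for growth rate, and the restriction to detected spike-ins, were chosen after the results were seen, and so were the genes of the next paragraph.

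Transcripts of the mitochondrial genome went both ways in BH13. Of the 14 measured genes that the gene table names, 8 were higher and 6 lower. Q0017, Q0182 and Q0297, mitochondrial probes under the array's own names, are not counted here. Their signal was higher on every BH13 array than on any REF array. COX1 rose by 3.07 ± 0.21, COX2 by 2.90 ± 0.22, ATP6 by 2.64 ± 0.28 and COB by 2.47 ± 0.20 on the log2 scale, all subunits of the respiratory chain or ATP synthase, while ATP8, another ATP synthase subunit, fell by 1.44 ± 0.34. The intron-encoded BI2 fell by 4.15 ± 0.37, AI5_BETA by 3.13 ± 0.28 and AI1 by 2.98 ± 0.29, and VAR1, a mitochondrial ribosomal protein gene, fell by 2.78 ± 0.40. The intron-encoded AI2 and AI5_ALPHA rose, by 0.98 ± 0.24 and 0.98 ± 0.32. REF replicate 3, the only array on its slide, was the highest REF array for each of the 14 genes. Without it the differences of BI2, AI1 and VAR1 were -3.64, -2.59 and -2.24. Those of genes that rose became larger, such as 3.23 for COX1 and 2.97 for ATP6, with 8 genes still called higher and 6 lower. BI2 was well above background on 1 of the 3 BH13 arrays. The maltase genes MAL12 and MAL32, near-identical copies, were higher by 4.89 ± 0.23 and 4.33 ± 0.24. The medians of the 16 nuclear chromosomes lay between -0.20 and 0.14.

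The a-cell and haploid-specific genes were lower in BH13, with a joint median of -3.59 over 17 genes. An effect on probes that ignores gene function is argued against, because the lowest median among 10000 random lists matched on mean signal was -1.28. The random lists came from the same arrays as the list calls and treat genes as independent, so they are not separate evidence. A candidate explanation is that the BH13 RNA came from a/alpha cells, in which these genes are repressed. It predicted that NEJ1 and RDH54, haploid-specific genes outside the lists, would be lower, and they were, at -2.79 ± 0.15 and -1.86 ± 0.09 with a median of -2.32, and that the alpha2 probes would be higher, as HMLALPHA2 at 3.31 ± 0.11 and MATALPHA2 at 3.34 ± 0.12 were. IME4, needed for entry into meiosis, was higher by 7.62 ± 0.10, or 3.68 with normexp background correction, but was not in the prediction. The meiosis and sporulation list, with 8 of 15 genes higher and 6 lower, was not called. Other rows do not go with the a/alpha explanation as plainly. HMLALPHA1 at 2.02 ± 0.14 and MATALPHA1 at 1.99 ± 0.15 were higher, and a/alpha cells repress alpha1. A rise over REF does not decide whether alpha1 was repressed in BH13, since its REF signals were lower still, at -4.84 and -4.86. Its BH13 signals were -2.83 and -2.87, against 2.49 and 2.48 for the alpha2 probes, though different probes are not directly comparable. HMRA1 was higher at 1.95 ± 0.25, although a cells express a1 too, and FUS1 was not lower. The alpha2 probes may also read the HMRA2 copy, at 3.26 ± 0.12, and a different strain or culture on the BH13 arrays stays open, since ploidy and mating type are not in the labels.

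The breadth of the difference, 4789 genes called, has open technical explanations. The highest number called in another split of the 6 arrays was 0, and the real split was the 1 of 10 with as many, but 10 splits are too few for a share under 0.05. The same holds for the 2089 genes called at least 2-fold apart, where the highest other was 0 and 1 split gave as many. For the 15 lists, 3 of 10 splits gave as many and the highest other was 17. Each group of another split holds 2 arrays of one strain and 1 of the other, so the strain difference widens the spread within groups. Calls of genes are then all but prevented, and the counts of 0 say little about whether the real counts arose by chance. Part of the strain difference also stays between such groups, so the list counts give no baseline without that difference. A batch effect cannot be told apart from the strain, as no slide held both. With the slide as a random block 4710 genes were called, but that block rests on slide differences among the REF arrays only and cannot decide. The scanner or hybridisation response could contribute, because the 14 spike-in transcripts had an SD of 0.68 against 1.30 over genes, between the bounds set beforehand. Over the 7 detected spike-ins alone the SD was 0.29, past the lower bound, but that subset was chosen after the values were seen. A labelling or degradation bias with gene length also stays open, as Spearman's rho across 5601 genes was -0.17, between the bounds of 0.1 and 0.3 in size.

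Stress genes were higher and ribosome biogenesis genes lower in BH13, a pairing known from slow or stressed growth. Glucose exhaustion at harvest could not be settled. The 6 strongly glucose-repressed genes PCK1, FBP1, ICL1, MLS1, JEN1 and ACS1 had a median of 0.95 with an SD of 0.84, not clearly below the bound of 1, while the highest was 1.99 where exhaustion was taken to need a median of 3. Outside these 6, genes of sugar and alcohol use went both ways. HXT7 was at 5.10 and MAL12 at 4.89, but GAL1 was at -1.11 and ADH2 at -0.86. A lower growth rate of BH13 likewise may or may not contribute, because the ribosomal protein list had a median of -0.37 and was not called, short of the -0.5 and the call that a lower growth rate was taken to need. The list was called lower under 4 of 16 alternatives, with a median of -0.47 at the lowest, with quantile normalization. The mutations of BH13 stay among the open explanations, untested here.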
